A study of Mus musculus with 22 samples.

How the data were processed

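RNA of mouse bone marrow cells, sorted by CD45 and Sca1, was measured on Affymetrix MOE430A and MOE430B arrays, 1 array of each chip for each of 11 RNA samples. The deposited values are linear signal intensity per probe set, and per the submitters' processing notes they come from MAS5, whose version is not given in the sources used here. On every array the mean of the deposited intensity values, after the lowest and highest 2% were removed, was 1500, so each array had been scaled by 1 factor by the authors. No detection calls were used here. The other deposited files are text records of the array runs, per the file headers, with the chip lot, the fluidics station, a hybridization time and the sample description. They served for batches and for the order of the sort signs and hold no measurement. Wash runs were inferred here, for each chip, from gaps between the recorded hybridization times. Groups were taken from the sample labels, with 3 samples each of OGCsort -/-, +/- and +/+ and 2 of CPGSE +/+. The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, apart from the tests and the alternative that the closing section names.

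Each array was rescaled to a trimmed mean of 500 and the values were taken as log2(signal + 32). A probe set was kept where its rescaled signal was over 100 on at least 2 of the 11 arrays of its chip. Control probe sets were left out, and the 100 probe sets printed on both chips were taken from chip A. This left 19273 probe sets on chip A and 21255 on chip B, 40528 in all. The probe tables name a single gene for 20380 of 22626 probe sets of chip A, several genes for 691 and none for 1555. On chip B they name a single gene for 14661 of 22511, several for 245 and none for 7605. Of these 35041 single-gene probe sets 34837 had a gene identifier found in the reference gene table, and 0 symbols differed from it.

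Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a mean-variance trend), each chip fitted by itself, with Benjamini-Hochberg adjustment over the probe sets of both chips and a threshold of 0.05. The 3 comparisons within OGCsort used the 9 OGCsort samples, and the comparison with CPGSE used all 11. A gene was represented by 1 probe set: chip A before chip B, then a name ending in _at without a further letter, then the highest mean. Ptprc was also tested by an exact permutation test. Folds were taken from the log2 fold change, so they differ from the ratio of the mean signals printed beside them. Where every array of a group was under a signal of 100, a fold was computed against 100 and is given as a bound.

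The genes named in each comparison were drawn from Ptprc, Ly6a, the 12 rises and 12 falls with the largest log2 fold change among genes with an adjusted p under 0.05, a log2 fold change of at least 1 and no overlap between samples, and up to 4 members of each list with the smallest adjusted p; predicted genes and clone names were skipped. Not all of them are printed. There were 20 lists: erythroid; haem synthesis; stem and progenitor; B lymphoid; plasma cell; T and NK lymphoid; neutrophil granule; monocyte and macrophage; MHC class II presentation; dendritic; megakaryocyte and platelet; basophil, mast cell and eosinophil; endothelial; mesenchymal stromal; osteoblast; myogenic; cell cycle; interferon response; immediate early and heat shock; cytosolic ribosome. They hold 468 genes, of which the probe tables name no probe set for 43, and 18 more were below the signal filter. In all, 12 genes are in more than 1 list. Of the genes of a list, another list also holds 1 of the erythroid, 1 of the haem synthesis, 4 of the stem and progenitor, 1 of the plasma cell, 1 of the T and NK lymphoid, 1 of the monocyte and macrophage, 5 of the dendritic, 2 of the megakaryocyte and platelet, 3 of the endothelial, 1 of the mesenchymal stromal, 2 of the osteoblast and 2 of the interferon response genes. The other 8 lists share no gene. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a comparison. The alternatives were camera with an estimated correlation, which asks the same question with a correlation taken from the residuals, and fry, which asks whether a list's genes move on balance to one side.

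The alternatives also covered the pseudocount, the filter, quantile normalization, no rescaling, eBayes without a trend or robust, array weights, adjustment within a chip, the sort number as a random block, the wash run and station as a block, all 11 samples in the fit, the CPGSE samples in place of the OGCsort +/+ samples, and leaving out each sample in turn. The block of wash run and station was the wash run alone on chip A and the wash run with the station on chip B. The scripts were tested on simulated data with the real mean levels and spreads of 40528 probe sets, of which 200 were changed. For the comparison of 3 +/+ with 3 -/- samples 1.49% of 2-fold, 25.4% of 4-fold and 68.2% of 8-fold changes were recovered, with 3 false calls among 66. For 3 OGCsort against 2 CPGSE +/+ samples 1.49, 17.9 and 63.6% were recovered, with 3 false calls among 58. No changed probe set was called in the wrong direction. An earlier bound on the share of 8-fold changes recovered lay above both of these shares and was dropped, since the estimated changes lay near the simulated ones. When the MHC class II list was shifted by 1 on the log2 scale, camera gave it an adjusted p of 6.69e-05 in the first comparison and 2.16e-06 in the other, with 0 other lists called. With an estimated correlation the adjusted p were 0.357 and 0.144. The simulated probe sets varied independently of each other, so this cannot show how often camera calls lists whose genes vary together. In the data the estimated correlation of the B lymphoid list was 0.56 in +/+ against -/-. Figures were drawn in Python with matplotlib.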

Results

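The series measured RNA from mouse bone marrow cells that had been stained for CD45, a phosphatase on the surface of white blood cells, and for Sca1, a surface antigen found on blood stem cells and on some mature lymphocytes and myeloid cells. Cells were sorted by which of the markers they carried, and each of 11 RNA samples was hybridized to a pair of chips, MOE430A and MOE430B, which gave 22 arrays. The set named OGCsort held 3 samples without either marker (-/-), 3 samples with the first marker alone (+/-) and 3 samples with both (+/+), at a stated purity of 90%. The set named CPGSE held 2 further +/+ samples at a stated purity of 95-98%, with haematopoietic stem cells of the bone marrow given as their source. The records of the array runs give the order of the signs in the OGCsort set as CD45 first and Sca1 second. The labels do not say whether the samples of a group came from separate animals, so the p-values measure only the spread between these samples. The number of arrays limits the precision. A rescaled signal above 100 was found for 63.3 to 70.6% of the probe sets on the chip A arrays and for 72.3 to 80% on the chip B arrays.

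Ptprc, the gene of CD45, was read first as a check on the labels. Its signal was 533 ± 552 (SD, n = 3) in the -/- samples, 8050 ± 668 (n = 3) in +/-, 10600 ± 1660 (n = 3) in OGCsort +/+ and 13300 ± 1830 (n = 2) in CPGSE +/+. Ptprc was 25.7-fold higher in +/+ than in -/- (log2 fold change 4.69, SE 0.48, limma adjusted p = 1.61e-05) and 19.6-fold higher in +/- than in -/- (log2 fold change 4.30, adjusted p = 4.52e-05). These folds were 17.3 and 13.2 without -/- sample 8, and 44 and 33.6 without -/- sample 4. With the wash run of the chip A arrays as a block the first kept its call (log2 fold change 4.57, adjusted p = 0.000338) and the second did not (log2 fold change 3.96, adjusted p = 0.0569). An exact two-sided permutation test gave p = 0.1 for both, the smallest p that 3 samples against 3 allow. Between +/+ and +/- the log2 fold change of Ptprc was 0.39 (adjusted p = 0.973, exact p = 0.1). Between the OGCsort and CPGSE +/+ samples it was -0.33 (adjusted p = 0.973, exact p = 0.3). The other Ptprc probe set, on chip B, was 24.1-fold higher in +/+ and 20.6-fold higher in +/- than in -/-. Its log2 fold change between +/+ and +/- was 0.22 (adjusted p = 0.987, exact p = 0.6). The probe tables gave no probe set the name of Ly6a, the gene of Sca1, alone, so this marker was not checked by name. Whether a probe set without a single gene name measures it was not tested.

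Some samples stood apart from the others of their group. In -/- sample 4 the signal of Ptprc was 1170, against 279 and 153 in samples 5 and 8, and that of Hemgn, an erythroid nuclear protein, was 29300 against 62300 and 47200. On the first principal component of chip A, which held 49.5% of the variance, -/- sample 4 lay at 79.3 and the other -/- samples at 133 and 139.8, while all +/- and +/+ samples were below 0. In +/- sample 1 the neutrophil gene Camp had a signal of 72200, against 14600 and 7650 in samples 7 and 9, and its run records carry a bracketed 2 whose meaning is not given. In OGCsort +/+ sample 1 the immunoglobulin joining chain gene Jchain had a signal of 14100, against 978 and 1030 in samples 5 and 6. The ratio of the 3' to the 5' control probe sets of Gapdh on chip A, a sign of RNA degradation or short transcripts, was 9.94 ± 1.82 (SD, n = 3) in -/-, 15.9 ± 3.24 in +/-, 16.9 ± 7.83 in OGCsort +/+ and 14.7 ± 0.42 (n = 2) in CPGSE +/+. In +/+ sample 6 it was 9.14, within the 8.17 to 11.8 of the -/- samples. It was highest in +/+ sample 1 (24.8) and +/- sample 1 (19.6), which also stood apart as given above. On chip B the Gapdh ratios of these samples were 20.9 and 22. The same ratio for actin on chip A was 6.75 ± 1.37, 6.87 ± 0.56, 8.73 ± 4.44 and 4.66 ± 0.148, in the same order of groups. It was 12.9 in +/+ sample 1 and 7.18 in +/- sample 1. Whether RNA quality set these samples apart was not tested. Over the 100 probe sets printed on both chips, the chip A array correlated best with its own chip B array in 9 of 11 samples. In -/- sample 5 the correlation was 0.758 with its own and 0.854 with the chip B array of -/- sample 8, and in +/+ sample 5 it was 0.446 with its own and 0.524 with that of +/+ sample 1. The chip A arrays of these partners matched their own best, with 0.885 in -/- sample 8 (0.668 with the best other) and 0.559 in +/+ sample 1 (0.298 with the best other), which argues against an exchange.

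**Figure D1:**
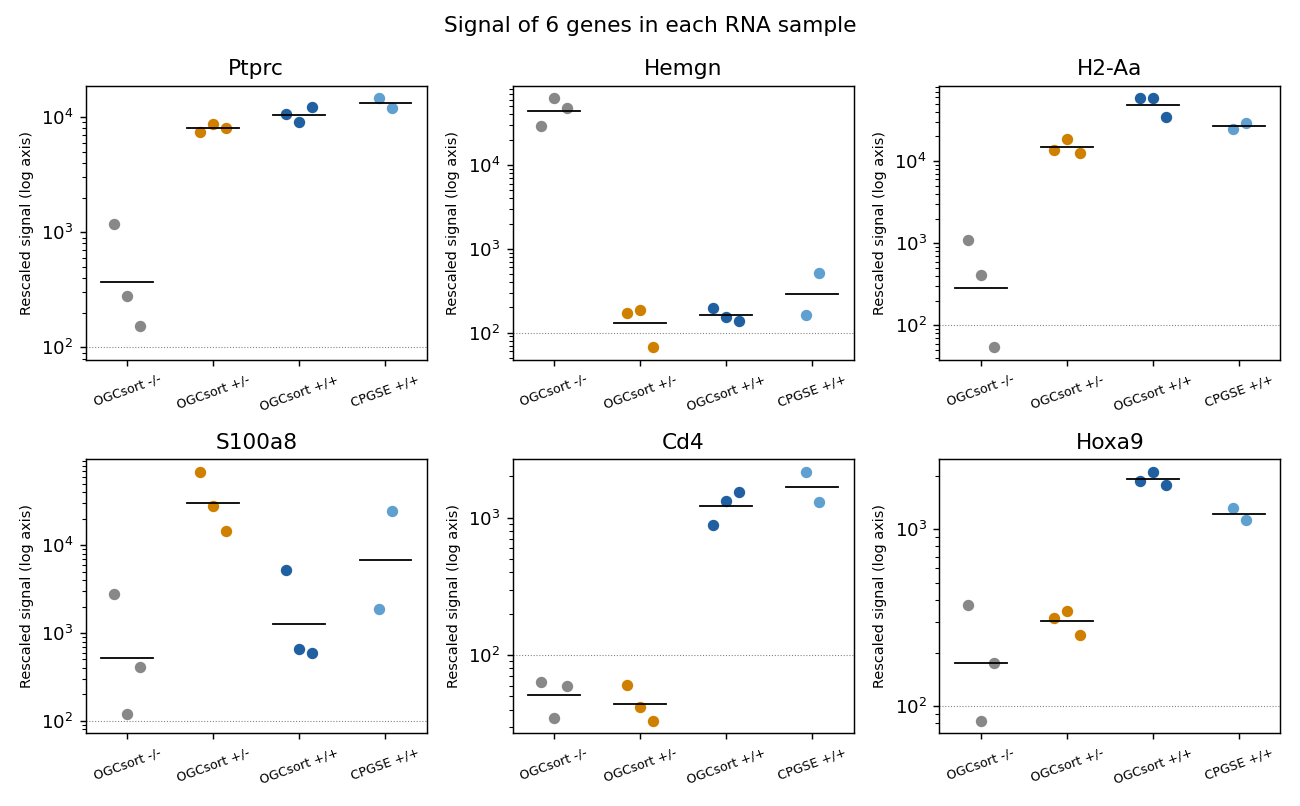
Rescaled signal (log axis) of 6 genes in each RNA sample, by group; points are samples, bars are geometric means and the dotted line is a signal of 100. Hemgn lay between 29300 and 62300 in the -/- samples and between 66.6 and 516 in all others, and Cd4 lay between 878 and 2160 in the +/+ samples of both sets.

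The comparison of +/+ with -/- cells asked which transcripts go with carrying both markers rather than neither. The -/- samples were rich in red cell transcripts and the +/+ samples in transcripts of antigen presentation and of lymphocytes. Hemgn fell from 46300 ± 16500 (SD, n = 3) in -/- to 163 ± 31 (n = 3) in +/+, a 229-fold difference (log2 fold change -7.84, SE 0.34, adjusted p = 1.39e-08). H2-Aa, a chain of the MHC class II molecule that presents peptides to T cells, rose from 520 ± 529 to 50100 ± 13800, a 139-fold difference (log2 fold change 7.12, SE 0.64, adjusted p = 5.52e-06) that became 68.9-fold without -/- sample 8 and 249-fold without -/- sample 4. Across 40528 probe sets, 6784 passed an adjusted p of 0.05 by limma, 3913 higher and 2871 lower in +/+. Cd52, a surface glycoprotein of lymphocytes and myeloid cells, rose 45.2-fold (36.2-fold without -/- sample 5, 70.3-fold without -/- sample 4). Of 45 named genes, 12 had a fold that moved over 1.5 times when a sample was left out and both groups stayed measured, 8 of them without -/- sample 4. With 1 probe set per gene, 1844 genes rose and 1466 fell among 17027 named genes.

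Of 23 measured genes of the erythroid list, 22 fell, and 23 fell when adjusted over the list alone. Rhd, a carrier of the Rh blood group, fell 157-fold, the anion exchanger Slc4a1 fell 116-fold, and Rhag, which forms a complex with Rhd, was at least 98.9-fold lower, since every +/+ array was under a signal of 100. Car2, a carbonic anhydrase abundant in red cells, fell 44.4-fold. The list had a median log2 fold change of -5.44 (camera adjusted p = 2.75e-31, and adjusted p = 0.0306 with an estimated correlation). All 10 measured genes of the haem synthesis list fell, by either adjustment, among them Alad (21.2-fold) and the ferrochelatase gene Fech (28.2-fold), with a median of -4.33 (adjusted p = 1.13e-14, and adjusted p = 0.0304 with an estimated correlation). Of 35 cell cycle genes, 31 fell and none rose, and 34 fell when adjusted over the list alone. Mki67, a marker of dividing cells, fell 9.99-fold and Ube2c, an enzyme of mitotic exit, fell 17.5-fold. The cell cycle median was -2.24 (adjusted p = 1.12e-26, and adjusted p = 0.0506 with an estimated correlation).

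Among the lists that were higher in +/+, the MHC class II list had the highest median log2 fold change, 4.24 (adjusted p = 6.79e-09, and adjusted p = 0.0592 with an estimated correlation). Of its 9 measured genes 7 rose, by either adjustment, including H2-Ab1 (86.8-fold, and at least 114-fold without -/- sample 4) and Cd74, the invariant chain (18.8-fold). The T and NK lymphoid list had a median of 2.38 (adjusted p = 2.09e-11, and adjusted p = 0.0304 with an estimated correlation). Of its 28 genes, 17 rose and 1 fell (21 and 1 adjusted over the list alone). Klrd1, a receptor subunit of natural killer cells, was at least 21.5-fold higher and Cd4, a co-receptor of helper T cells, at least 12.2-fold higher. Of 23 B lymphoid genes, 11 rose (15 adjusted over the list alone), such as Ms4a1, which encodes CD20 (15.9-fold), and Cd22 (13.3-fold), with a median of 1.57 (adjusted p = 1.99e-08, and adjusted p = 0.236 with an estimated correlation). Of 16 plasma cell genes, 5 rose (7 adjusted over the list alone), among them Jchain (15.7-fold) and Mzb1 (5.66-fold, and 9.16-fold without -/- sample 4), with a median of 1.14 (adjusted p = 0.000663, and adjusted p = 0.0634 with an estimated correlation). Jchain was 6.59-fold higher without OGCsort +/+ sample 1 (adjusted p = 0.00216) and 24.6-fold without +/+ sample 5.

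Of 26 monocyte and macrophage genes, 12 rose and 1 fell, by either adjustment. The protease gene Ctss rose 44.8-fold, the pore protein gene Mpeg1 43-fold and Irf8, a transcription factor of monocytes and dendritic cells, 26.5-fold. Ctss was 19.4-fold higher without -/- sample 8 and 99.5-fold without -/- sample 4, where Mpeg1 was at least 87.1-fold higher. The list's median was 0.98 (adjusted p = 2.56e-05, and adjusted p = 0.0634 with an estimated correlation). Of 15 dendritic genes, 8 rose (10 adjusted over the list alone), with a median of 1.81 (adjusted p = 7.29e-06, and adjusted p = 0.0621 with an estimated correlation). They included Ccr9, a homing receptor of lymphocytes and plasmacytoid dendritic cells (at least 33.6-fold), Siglech (6.2-fold) and Tcf4 (24.9-fold by the probe set used, with 5 of its 6 probe sets called in that direction and 1 of the opposite sign). Tcf4 was 15.6-fold higher without -/- sample 8 and at least 46.8-fold without -/- sample 4. Of 25 neutrophil granule genes, 8 rose by either adjustment, such as Prtn3 (5.84-fold; 3.68-fold without -/- sample 8 and 10.3-fold without -/- sample 4) and the transcription factor Gfi1 (4.83-fold), with a median of 1.22 (adjusted p = 0.00105, and adjusted p = 0.438 with an estimated correlation).

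The stem and progenitor list moved both ways. Of 23 measured genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 1.33 (adjusted p = 0.000873, and adjusted p = 0.0634 with an estimated correlation). Cd34 was at least 6.8-fold higher, the homeobox gene Hoxa9 rose 9.16-fold and its partner Meis1 was at least 3.71-fold higher, whereas Tal1, a transcription factor of stem cells that also drives the red cell lineage, fell 20.9-fold. Of 28 interferon response genes, 12 rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 0.84 (adjusted p = 0.0111, and adjusted p = 0.326 with an estimated correlation). The immunoproteasome gene Psmb8 rose 23-fold (13.6-fold without -/- sample 8 and at least 35.7-fold without -/- sample 4), while the antiviral gene Rsad2 fell 18.4-fold from a signal of 87300 ± 11700 in -/-. Without OGCsort +/+ sample 6 the interferon list had an adjusted p of 0.0518, within a range up to 0.326 over its alternatives. Of 24 immediate early and heat shock genes, 17 rose and 1 fell (17 and 2 adjusted over the list alone), with a median of 1.91 (adjusted p = 3.52e-09, and adjusted p = 0.135 with an estimated correlation). Fos rose 10.8-fold (16.9-fold without -/- sample 4), Nr4a1 7.91-fold and the stress gene Atf3 was at least 8.6-fold higher; with the CPGSE samples in place of OGCsort +/+ Atf3 did not pass (adjusted p = 0.625). Of 22 cytosolic ribosome genes, 3 rose by either adjustment, among them Rps19 (1.98-fold), with a median of 0.59 (adjusted p = 0.0133, and adjusted p = 0.365 with an estimated correlation). Rps19 lost its call without -/- sample 5 (adjusted p = 0.0754), without +/+ sample 5 (adjusted p = 0.0503) and with the wash run and station as a block (adjusted p = 0.058), within a range up to 0.0754 over its alternatives.

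Signals did not overlap between +/+ and -/- samples for 34.9% of probe sets, where chance gives 10%. With the wash run of chip A and the station of chip B as a block, 3959 probe sets passed (2226 higher, 1733 lower). Within the chip A run that held 2 +/+ and 3 -/- samples 3270 probe sets passed. On chip B a single +/+ sample shared a station run with the 3 -/- samples, where 28 probe sets passed, a count that rests on that sample. All 3 +/+ and 3 -/- samples shared the chip B wash run, and with its stations pooled 1566 probe sets passed. Within the chip A run, which also sets the blocked values, the medians were -5.24 for the erythroid list, -4.24 for haem synthesis, -2.09 for cell cycle, 3.56 for MHC class II, 2.27 for T and NK lymphoid, 1.51 for B lymphoid, 1.00 for plasma cell, 1.42 for dendritic, 1.30 for monocyte and macrophage, 1.63 for neutrophil granule, 1.11 for stem and progenitor, 0.66 for interferon response, 1.95 for immediate early and heat shock and 0.53 for cytosolic ribosome. On chip A without the block, these medians were -5.44, -4.33, -2.14, 3.67, 2.38, 1.55, 1.05, 1.63, 0.98, 1.25, 1.29, 0.84, 1.91 and 0.63, in the same order. In the blocked fit 13 of these lists passed, and the interferon list did not (adjusted p = 0.102). With the block Mzb1 (log2 fold change 2.24 with it and 2.50 without, SE 0.73 and 0.50, adjusted p = 0.0818) and Rps19 (0.91 and 0.99, SE 0.28 and 0.25, adjusted p = 0.058) lost their calls.

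**Figure D2:**
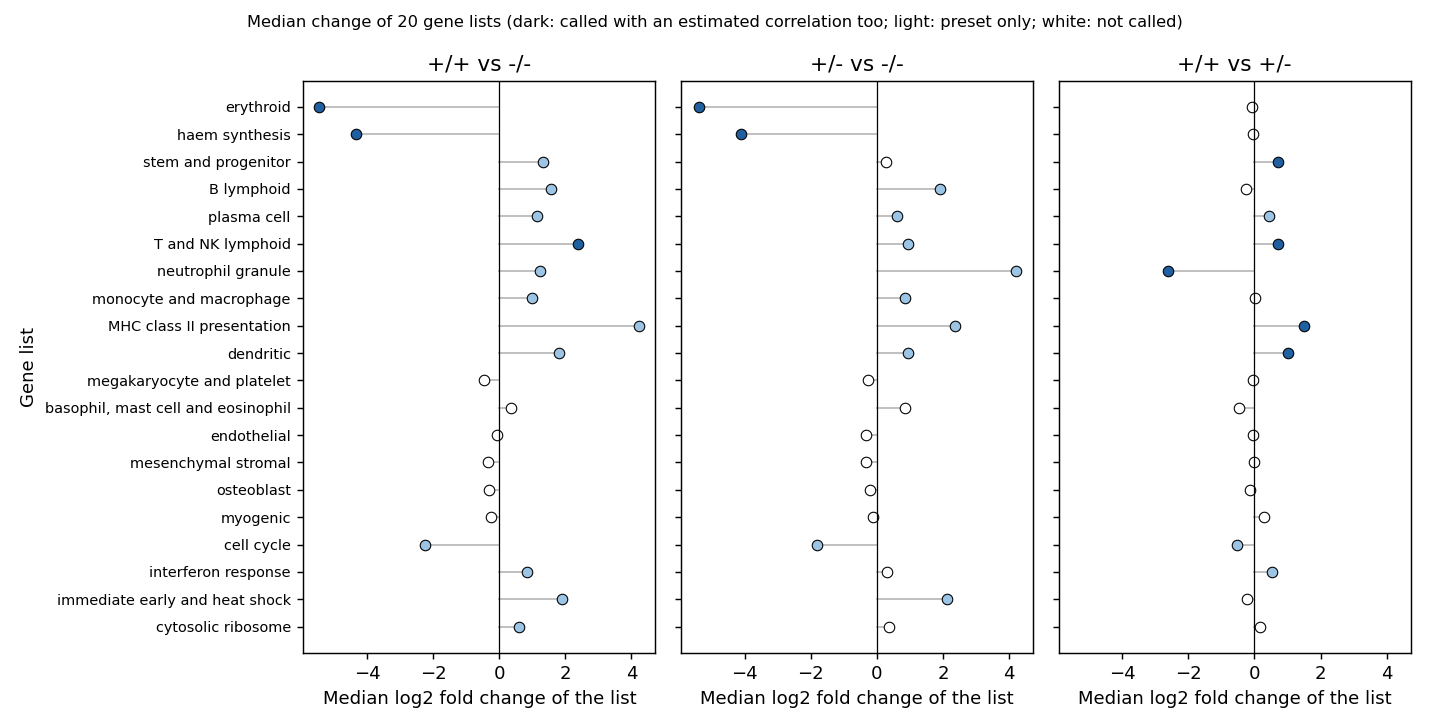
Median log2 fold change of 20 gene lists in each OGCsort comparison; dark points passed an adjusted p of 0.05 by camera with a preset and with an estimated correlation, light points only with the preset, and white points did not pass. The erythroid medians were -5.44 in +/+ against -/-, -5.39 in +/- against -/- and -0.09 in +/+ against +/-.

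The comparison of +/- with -/- cells asked which transcripts go with CD45 in cells without Sca1. The +/- samples were rich in neutrophil granule transcripts, and red cell transcripts were again lower than in -/-. Chil3, a chitinase-like protein of myeloid cells, rose from 135 ± 201 (SD, n = 3) in -/- to 19600 ± 17000 (n = 3) in +/-, a 151-fold difference (log2 fold change 7.24, SE 0.77, adjusted p = 3.06e-05) that became 94.6-fold without +/- sample 1 and at least 152-fold without -/- sample 4. Hemgn fell to 142 ± 65.2, a 270-fold difference (log2 fold change -8.08, SE 0.34, adjusted p = 1.38e-08). Of 40528 probe sets 5552 passed, 3180 higher and 2372 lower in +/-, and of 17027 named genes 1593 rose and 1220 fell. Of 41 genes named here, 15 had a fold that moved over 1.5 times when a sample was left out and both groups stayed measured, 10 of them without -/- sample 4 and 5 without +/- sample 1.

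Of 25 measured neutrophil granule genes, 20 rose and none fell, and 23 rose when adjusted over the list alone. The median log2 fold change was 4.21 (adjusted p = 4.28e-17, and adjusted p = 0.108 with an estimated correlation). The antimicrobial peptide gene Camp rose 85.7-fold, S100a9 65.6-fold, S100a8 53-fold and Lcn2 53.3-fold. Ngp, a neutrophil granule protein, rose 41-fold, the lysozyme gene Lyz2 33.4-fold and the myeloperoxidase gene Mpo 19.2-fold. Without -/- sample 4 these folds were 128 for S100a9, 117 for S100a8, 87.4 for Lcn2, 107 for Ngp, 53 for Lyz2 and 31.2 for Mpo, and Camp, with both remaining -/- arrays under a signal of 100, was at least 201-fold higher. Without +/- sample 1 Camp was 45.2-fold, S100a9 36.7-fold and Lcn2 28.5-fold higher, without -/- sample 5 S100a8 was 27.4-fold and Ngp 25.1-fold higher, and without -/- sample 8 Lyz2 was 21-fold and Mpo 14.1-fold higher. Sample 1 of +/- had the highest signal of its group for Camp (72200), S100a8 (68400), Chil3 (39000), Lcn2 (37000) and Ngp (93000). Of 26 monocyte and macrophage genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 0.84 (adjusted p = 0.000114, and adjusted p = 0.108 with an estimated correlation). Csf1r, the receptor of a macrophage growth factor, rose 20.6-fold and the Fc receptor gene Fcgr3 was at least 7.6-fold higher.

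Of 23 B lymphoid genes, 15 rose (18 adjusted over the list alone), including Ms4a1 (15.3-fold) and Cd22 (8.97-fold), with a median of 1.92 (adjusted p = 1.09e-09, and adjusted p = 0.196 with an estimated correlation). Of 28 T and NK lymphoid genes, 12 rose and 1 fell by either adjustment, such as Klrd1 (at least 11.8-fold) and the chemokine gene Ccl5 (16.6-fold, and 10.1-fold without -/- sample 5), with a median of 0.93 (adjusted p = 6.1e-06, and adjusted p = 0.0849 with an estimated correlation). Of 9 MHC class II genes, 7 rose by either adjustment, among them H2-Aa (42.2-fold; 20.9-fold without -/- sample 8 and 75.7-fold without -/- sample 4) and Cd74 (5.98-fold), with a median of 2.35 (adjusted p = 6.28e-06, and adjusted p = 0.108 with an estimated correlation). Of 15 dendritic genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Irf8 8.28-fold and Tcf4 7.06-fold higher and Irf7, a regulator of interferon genes, 2.53-fold lower. The dendritic median was 0.93 (adjusted p = 0.0437, and adjusted p = 0.29 with an estimated correlation). Its adjusted p was 0.0754 without -/- sample 5, 0.0506 without -/- sample 8, 0.0827 without +/- sample 7 and 0.103 without +/- sample 9. Tcf4 was 4.43-fold higher without -/- sample 8 and at least 13-fold without -/- sample 4, and had an adjusted p of 0.0514 without -/- sample 5, within a range up to 0.589 over its alternatives. Of 16 plasma cell genes, 5 rose by either adjustment, such as Edem1, a factor of protein disposal in the endoplasmic reticulum (5.66-fold), with a median of 0.62 (adjusted p = 0.0437, and adjusted p = 0.196 with an estimated correlation). The plasma cell list had an adjusted p of 0.0529 without -/- sample 8, 0.105 without +/- sample 7 and 0.0616 without +/- sample 9.

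Of 23 erythroid genes, 22 fell (23 adjusted over the list alone), with a median of -5.39 (adjusted p = 5.09e-34, and adjusted p = 0.0374 with an estimated correlation). Slc4a1 fell 135-fold, Rhd 130-fold, Car2 68.1-fold and Alas2, the first enzyme of haem synthesis in red cells, 72.8-fold. All 10 haem synthesis genes fell by either adjustment, with Fech 35.2-fold lower and a median of -4.09 (adjusted p = 1.28e-16, and adjusted p = 0.0374 with an estimated correlation). Sox6, a transcription factor of erythroid maturation, was at least 29.1-fold lower. Of 35 cell cycle genes, 31 fell and none rose (32 fell adjusted over the list alone), among them Ube2c (11.6-fold) and the cyclin gene Ccna2 (5.36-fold), with a median of -1.82 (adjusted p = 1.1e-22, and adjusted p = 0.0849 with an estimated correlation). Of 24 immediate early and heat shock genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), including Fos (10.5-fold, and 16.4-fold without -/- sample 4) and Atf3 (at least 13.5-fold), with a median of 2.11 (adjusted p = 1.13e-10, and adjusted p = 0.13 with an estimated correlation).

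The stem and progenitor list did not pass (median 0.28, adjusted p = 0.442). Of its 23 genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), with Cd34 at least 2.26-fold higher and Tal1 22-fold lower. The interferon response list did not pass either (median 0.29, adjusted p = 0.59). Of its 28 genes 7 rose and 5 fell (8 and 6 adjusted over the list alone), with Psmb8 16.1-fold higher (9.51-fold without -/- sample 8 and at least 24.8-fold without -/- sample 4) and Rsad2 30.1-fold lower. Signals did not overlap between +/- and -/- samples for 29.6% of probe sets, where chance gives 10%.

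The +/- and -/- samples never shared a wash run on chip A or a station run on chip B. On chip B +/- samples 7 and 9 shared a wash run with the 3 -/- samples at another station, and 516 probe sets passed there, where group and station cannot be told apart. A fit with the run and station as a block ties the groups only through the +/+ samples, of which sample 6 alone shared the chip A run of +/-. That fit called 512 probe sets, 194 higher and 318 lower in +/-. Of the 41 named genes, 25 kept an adjusted p under 0.05 in it, and 16 did not. These were Ptprc (log2 fold change 3.96 with the block and 4.30 without it, adjusted p = 0.0569), S100a9 (7.35 and 6.04, adjusted p = 0.0602), S100a8 (7.35 and 5.73, adjusted p = 0.0618), Lcn2 (6.65 and 5.74, adjusted p = 0.0512), Ngp (5.87 and 5.36, adjusted p = 0.143), Cd74 (2.24 and 2.58, adjusted p = 0.154), Cd22 (2.89 and 3.16, adjusted p = 0.0797) and Ccl5 (3.77 and 4.05, adjusted p = 0.0812). The others were Ccna2 (-1.75 and -2.42, adjusted p = 0.0626), Psmb8 (3.96 and 4.00, adjusted p = 0.148), Cpa3 (3.24 and 2.36, adjusted p = 0.0936), Cd34 (adjusted p = 0.372), Irf8 (2.41 and 3.05, adjusted p = 0.135), Tcf4 (1.83 and 2.82, adjusted p = 0.589), Edem1 (1.75 and 2.50, adjusted p = 0.292) and Gp9 (-3.22 and -2.25, adjusted p = 0.0556). Of the 15 measured in both groups the fold was smaller with the block for 9 and larger for 6, while the SE of all 16 was 1.63 to 1.91 times that without the block. On chip A the blocked list medians were -4.99 for the erythroid list, -4.05 for haem synthesis, -1.64 for cell cycle, 4.71 for neutrophil granule, 1.20 for monocyte and macrophage, 1.97 for B lymphoid, 0.47 for T and NK lymphoid, 1.75 for MHC class II and 2.47 for immediate early and heat shock, all of which passed. Without the block they were -5.39, -4.09, -1.72, 4.23, 0.84, 2.20, 0.93, 2.11 and 2.11 on that chip. The dendritic list (0.39, against 0.96 without the block; adjusted p = 0.569) and the plasma cell list (0.65, against 0.58; adjusted p = 0.246) did not pass with the block.

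The comparison of +/+ with +/- cells asked which transcripts go with Sca1 among cells that carry CD45. Some genes of the T and NK lymphoid, dendritic and MHC class II lists and the homeobox gene Hoxa9 were higher in +/+. Neutrophil granule genes and the fibronectin gene Fn1 were lower. Which cells carried these transcripts was not tested. Cd4 rose from 45.1 ± 13.7 (SD, n = 3) in +/-, where every array was under a signal of 100, to 1250 ± 341 (n = 3) in +/+, at least 12.2-fold (adjusted p = 0.001). Fn1 fell from 5560 ± 1170 to 611 ± 284, a 9.1-fold difference (log2 fold change -3.19, SE 0.29, adjusted p = 0.000498). Of 40528 probe sets 41 passed, 28 higher and 13 lower in +/+, and 2686 had an unadjusted p under 0.05. With 1 probe set per gene 14 genes rose and 7 fell. Signals did not overlap for 13.3% of probe sets, where chance gives 10%.

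Among the rises, Klk1, a kallikrein protease, was at least 15.4-fold higher, Ccr9 rose 20.5-fold and the related kallikrein Klk1b27 was at least 3.51-fold higher. Sh3bgr was at least 3.95-fold higher, Pltp, a phospholipid transfer protein, rose 6.72-fold, Ptprf, a receptor phosphatase, 5.7-fold and Kbtbd11 4.91-fold, and 1 probe set of each of Sh3bgr, Ptprf and Kbtbd11 had the opposite sign. Gimap4, a GTPase of lymphocytes, rose 4.58-fold. Besides Fn1, the falls with 1 probe set per gene were Lcn2 (24.3-fold), the haptoglobin gene Hp (17.3-fold) and the coagulation factor gene F13a1 (5.29-fold). The others were the collagen gene Col5a3 (5.13-fold), the stress gene Gadd45a (3.17-fold) and E2f8, a cell cycle transcription factor (2.98-fold). Over all probe sets, 18 named genes were called higher and 10 lower. Without +/- sample 1 Ccr9 was 13.4-fold higher, Lcn2 13-fold lower and Hp 10.8-fold lower, and without +/+ sample 1 they were 28.9-fold, 39.2-fold and 26.6-fold. The probe set with the smallest adjusted p has no single gene name in the probe tables, and which gene it measures was not determined here. Its signal was 897 ± 150 in -/-, 1260 ± 405 in +/- and 18600 ± 4070 in +/+ (log2 fold change 3.89, SE 0.28, adjusted p = 5.14e-05).

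Of the 8 lists that passed in this comparison, 5 also passed with an estimated correlation. Other splits of the same samples called up to 10 lists, as given in the closing section. The MHC class II list had a median log2 fold change of 1.51 (adjusted p = 7.89e-11, and adjusted p = 0.0417 with an estimated correlation). Of its 9 genes 1 rose, H2-Eb1 (6.78-fold). H2-DMb2 passed only by a probe set other than the one used for it (log2 fold change 2.06, adjusted p = 0.0453). When adjusted over the list alone 7 rose, among them H2-Ab1 (6.14-fold, adjusted p = 0.0823 over all genes) and Cd74 (3.15-fold, adjusted p = 0.117 over all genes). The dendritic list had a median of 1.01 (adjusted p = 4.39e-10, and adjusted p = 0.0395 with an estimated correlation). Of its 15 genes 2 rose, Ccr9 and Siglech, a receptor of plasmacytoid dendritic cells (5.31-fold), and 9 rose adjusted over the list alone. Irf8 (3.2-fold, adjusted p = 0.149), Bst2 (6.21-fold, adjusted p = 0.392) and Irf7 (2.01-fold, adjusted p = 0.263) did not pass over all genes, and Bst2 was 3.65-fold without +/- sample 1 and 10.7-fold without +/+ sample 1. The T and NK lymphoid list had a median of 0.70 (adjusted p = 5.49e-09, and adjusted p = 0.0395 with an estimated correlation), with Cd4 and Gimap4 rising among 28 genes, 6 rising and 1 falling adjusted over the list alone, and Cd3d at 3.13-fold (adjusted p = 0.261). The stem and progenitor list had a median of 0.72 (adjusted p = 3.53e-09, and adjusted p = 0.0395 with an estimated correlation). Of its 23 genes 1 rose, Hoxa9, from 305 ± 45.7 to 1920 ± 176 (5.82-fold), and 8 rose adjusted over the list alone. Meis1 was 4.28-fold (adjusted p = 0.169), Hlf 2.97-fold (adjusted p = 0.0842) and Cd34 2.76-fold (adjusted p = 0.216) higher. The other probe set of Hlf passed (log2 fold change 2.67, adjusted p = 0.0447).

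The neutrophil granule list was lower in +/+, with a median of -2.61 (adjusted p = 3.16e-29, and adjusted p = 0.0467 with an estimated correlation). Of its 25 genes 2 fell, Lcn2 and Hp, and 22 fell adjusted over the list alone, while Chil3 (20.9-fold lower) and Itgb2l (10.3-fold lower) both had an adjusted p of 0.0501 over all genes. Chil3 was 13.1-fold lower without +/- sample 1 and 32-fold without +/+ sample 1. Itgb2l was 5.91-fold lower without +/- sample 1 and passed without +/- sample 9 (16.1-fold, adjusted p = 0.0282), and 2 of its 3 probe sets had the opposite sign. In +/- sample 1 the neutrophil genes were higher than in the other samples of its group, as given above. The plasma cell list had a median of 0.44 (adjusted p = 0.0261, and adjusted p = 0.19 with an estimated correlation), with 0 of its 16 genes called by limma over all genes and 1 rising adjusted over the list alone. Its adjusted p was 0.168 without +/- sample 1 and 0.0969 without +/+ sample 6. Jchain was 12.2-fold higher (adjusted p = 0.104; 5.11-fold without +/+ sample 1 and 19.1-fold without +/+ sample 5), with a signal of 14100 in +/+ sample 1 and 978 and 1030 in the others. The interferon response list had a median of 0.52 (adjusted p = 2.77e-07, and adjusted p = 0.108 with an estimated correlation). The cell cycle list had a median of -0.53 (adjusted p = 1.22e-10, and adjusted p = 0.18 with an estimated correlation), with Top2a 1.69-fold lower (adjusted p = 0.394) and Bub1b 1.77-fold lower (adjusted p = 0.426). None of the 28 interferon and 35 cell cycle genes passed by limma over all genes or adjusted over the list alone.

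Of the 19 named genes that passed, Cd4 and Fn1 kept an adjusted p under 0.05 in all 21 alternatives, with highest values of 0.0398 and 0.0276, and the other 17 did not. The 41 probe sets became 9 without +/- sample 1, 22 without +/- sample 9, 12 without +/+ sample 5 and 10 without +/+ sample 6. Of the 19 genes, 16 lost their call without +/- sample 1, 11 without +/- sample 7, 14 without +/- sample 9, 8 without +/+ sample 1, 16 without +/+ sample 5 and 17 without +/+ sample 6. With the wash run and station as a block 6 probe sets passed, and 16 of the 19 genes lost their call. Of 13 of these, measured in both groups, the fold was larger for 11 and smaller for 2. Within the chip A run that held 1 +/+ and 3 +/- samples 50 probe sets passed, a count that rests on the single +/+ sample 6. Within the chip B station run with 2 samples of each group limma called 0 probe sets (1368 at an unadjusted p under 0.05), and within the chip B wash run of 3 +/+ and 2 +/- samples, its stations pooled, 1 passed. In the chip A run, whose 1 +/+ sample also sets the blocked values, the medians were 1.34 for the MHC class II list (1.45 on chip A without the block), 1.28 for dendritic (0.97), 1.01 for T and NK lymphoid (0.70), 0.64 for stem and progenitor (0.66), -2.98 for neutrophil granule (-2.70), 0.54 for plasma cell (0.37), 0.71 for interferon response (0.52) and -0.61 for cell cycle (-0.53). All 8 lists passed in the blocked fit, where +/+ sample 6 stood alone too, and 4 others passed there and not without the block: the erythroid (-0.28, adjusted p = 0.0362), immediate early and heat shock (-0.44, adjusted p = 0.0203), basophil, mast cell and eosinophil (-0.35, adjusted p = 0.0281) and mesenchymal stromal (-0.29, adjusted p = 0.0313) lists.

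The comparison of OGCsort +/+ with CPGSE +/+ cells set side by side the samples of both sets that carry the same signs. The sets differ in the stated purity, the sorter, the RNA method, the chip lots and the wash runs, so the set and the batch cannot be told apart. Limma called 0 of 40528 probe sets (2429 at an unadjusted p under 0.05; smallest adjusted p = 0.294), and signals did not overlap for 26.9%, where chance gives 20% for 3 samples against 2. Without CPGSE sample 6 the count was 1, and without OGCsort sample 1 it was 3. The stress gene Atf3 had a signal of 893 ± 298 (SD, n = 3) in OGCsort and 116 ± 136 (n = 2) in CPGSE (7.97-fold, adjusted p = 0.294; 3.66-fold without CPGSE sample 4). Without CPGSE sample 6 Atf3 passed, at least 8.6-fold higher (adjusted p = 0.0234). With 1 CPGSE sample left, a p-value of a gene or list rests on the spread of the OGCsort samples alone. Dusp1, a phosphatase induced by stress, was 3.75-fold higher in OGCsort (adjusted p = 0.294), Nr4a1 2.72-fold (adjusted p = 0.352) and Fosb 3.74-fold (adjusted p = 0.371).

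By camera 5 lists passed (8 without OGCsort sample 6), and none of them did with an estimated correlation. The immediate early and heat shock list was higher in OGCsort, with a median of 0.69 (adjusted p = 1.57e-07, and adjusted p = 0.471 with an estimated correlation) and 8 of 24 genes higher adjusted over the list alone. The neutrophil granule list was lower in OGCsort, with a median of -1.17 (adjusted p = 3.34e-08, and adjusted p = 0.494 with an estimated correlation). Its median was -0.15 without CPGSE sample 6 (adjusted p = 0.443), a sample in which S100a8 had a signal of 24500 against 1870 in CPGSE sample 4. Lyz2 was 3.54-fold (adjusted p = 0.672), Chil3 6.66-fold (adjusted p = 0.688) and S100a9 5.73-fold (adjusted p = 0.839) lower in OGCsort. Chil3 was 2.56-fold and S100a9 1.5-fold lower without CPGSE sample 6, and 17.4-fold and 21.9-fold without CPGSE sample 4. The monocyte and macrophage list had a median of -0.90 (adjusted p = 6.42e-09, and adjusted p = 0.295 with an estimated correlation), with the haem oxygenase gene Hmox1 4.35-fold (adjusted p = 0.529) and the chemokine receptor gene Cx3cr1 2.27-fold (adjusted p = 0.583) lower. The interferon response list had a median of -0.41 (adjusted p = 1.58e-05, and adjusted p = 0.471 with an estimated correlation), and adjusted p was 0.0598 without CPGSE sample 4. Irgm1 (2.06-fold, adjusted p = 0.46) and Ifi47 (2.03-fold, adjusted p = 0.525) were lower in OGCsort, and 2 of the 28 interferon genes passed adjusted over the list alone. The cell cycle list had a median of -0.32 (adjusted p = 0.00106, and adjusted p = 0.709 with an estimated correlation), with Cdca8 2.75-fold (adjusted p = 0.579; 1.53-fold without CPGSE sample 6 and 4.95-fold without CPGSE sample 4) and Nusap1 1.99-fold (adjusted p = 0.649; 1 of its 2 probe sets had the opposite sign) lower, and a median of 0.17 without CPGSE sample 6 (adjusted p = 0.203). Jchain was 6.45-fold lower in OGCsort (adjusted p = 0.563) and passed at 15.4-fold without OGCsort sample 1 (adjusted p = 0.013), with 14100 in OGCsort sample 1 and 13500 and 18800 in the CPGSE samples.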

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

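The alternative that leaves out -/- sample 4 and +/- sample 1 together, and the chip B wash run taken without its stations, were chosen after seeing the data; the others were planned. The named genes kept their direction in all alternatives run. In +/+ against -/- the 6784 probe sets became 3959 with the wash run and station as a block and 4667 to 7224 when a sample was left out. In +/- against -/- the 5552 became 512 with the block and 3763 to 6223 when a sample was left out. In +/+ against +/- the 41 became 14 with pseudocount 1, 106 with pseudocount 100, 23 with no filter, 20 with no rescaling, 18 without a trend, 189 with array weights, 79 with adjustment within each chip, 131 with the sort number as a random block, 6 with the wash run and station as a block, 75 with all 11 samples in the fit, 128 with the CPGSE samples in place of OGCsort +/+, and 9 to 36 when a sample was left out. In OGCsort against CPGSE +/+ the 0 became 115 with array weights and 0 to 3 when a sample was left out. Leaving out both doubted samples gave 7507, 6011 and 37 probe sets in the 3 OGCsort comparisons, and 14, 12 and 8 lists.

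With an estimated correlation the 14, 11, 8 and 5 lists called became 3, 2, 5 and 0, and with fry 14, 12, 5 and 0. When a sample was left out the lists called were 13 to 14, 9 to 12, 7 to 11 and 4 to 8. The cell cycle list in OGCsort against CPGSE +/+ had a median of -0.72 without CPGSE sample 4 and reversed to 0.17 without CPGSE sample 6. The cause was not tested for any of these. Among alternatives for single lists 432 kept the direction and the side of the threshold, 51 kept the direction and lost the call and 1 reversed; for named genes these numbers were 2496, 205 and 0, and 33 gained a call. Of the named genes that passed, 42 of 45 in +/+ against -/-, 25 of 41 in +/- against -/- and 2 of 19 in +/+ against +/- passed in every alternative. No paired analysis was possible because any 2 groups share at most 1 sort number.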

Other observations

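The tests of sample 4, apart from that of a higher background, and the test of sex-linked transcripts were chosen only after the results were seen, and the second dendritic list was chosen after the fixed lists had been tested and before its own test. The megakaryocyte, basophil, endothelial, mesenchymal, osteoblast and myogenic lists did not pass by camera with all samples and no block. By fry the endothelial list passed in +/+ (adjusted p = 0.0173) and in +/- (adjusted p = 0.00417), each against -/-. In +/+ against -/- the megakaryocyte and platelet list had a median log2 fold change of -0.45 (adjusted p = 0.891), with 3 genes higher and 2 lower of 20, the same when adjusted over the list alone. Its members went apart: Itgb3, an integrin subunit of platelets and other cells, was at least 27.8-fold higher, whereas Gp9, a platelet glycoprotein, fell 7.00-fold. In +/- against -/- the list had a median of -0.27 (adjusted p = 0.936), with Itgb3 at least 18.1-fold higher and Gp9 4.77-fold lower, and in +/+ against +/- it had a median of -0.05 (adjusted p = 0.927). The basophil, mast cell and eosinophil list had a median of 0.35 (adjusted p = 0.537) in +/+ and 0.86 (adjusted p = 0.0959) in +/-, each against -/-, and in +/- the basophil protease gene Mcpt8 rose 10.5-fold and the mast cell protease gene Cpa3 5.14-fold (3.36-fold without -/- sample 4). In +/+ against +/- its median was -0.47 (adjusted p = 0.07).

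The endothelial list had a median of -0.06 (adjusted p = 0.27) in +/+ against -/-, where the receptor gene Adgrl4 rose 2.66-fold and Cd36, a fatty acid transporter also found on red cell precursors, fell 21.5-fold (14.1-fold without +/+ sample 1). The mesenchymal stromal list had a median of -0.33 (adjusted p = 0.323), with Vcam1 at least 5.54-fold higher by 1 of its 3 probe sets and the collagen gene Col5a1 5.09-fold lower. Fn1 of that list rose 7.72-fold in +/- against -/-. The osteoblast list had a median of -0.32 (adjusted p = 0.537), with 0 of 9 genes called by limma over all genes or adjusted over the list alone. The myogenic list had a median of -0.26 (adjusted p = 0.891), and its member Mef2c, a transcription factor of muscle and also of B and myeloid cells, rose 15.6-fold (8.92-fold without -/- sample 8 and 28.3-fold without -/- sample 4). In +/- against -/- these 4 lists had medians of -0.33, -0.33, -0.22 and -0.12, and in +/+ against +/- of -0.04, -0.03, -0.13 and 0.30, and none passed by camera without the block. The B lymphoid list had a median of -0.27 (adjusted p = 1) in +/+ against +/-, the monocyte and macrophage list 0.03 (adjusted p = 0.517) and the erythroid list -0.09 (adjusted p = 0.687). Median and mean differed in sign for 2 lists in +/+ against -/- (megakaryocyte and platelet, myogenic), 1 in +/- against -/- (megakaryocyte and platelet), 2 in +/+ against +/- (haem synthesis, endothelial) and 3 in OGCsort against CPGSE (erythroid, haem synthesis, MHC class II), and the test took the side of the median, except in +/+ against +/-, where it took that of the mean, and for the erythroid and haem synthesis lists against CPGSE, where it also took that of the mean. In +/+ against +/- the test of the mesenchymal stromal and megakaryocyte and platelet lists pointed up while median and mean were under 0.

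The 6 samples of each OGCsort comparison can be split 10 ways, too few for a share under 0.05. The real split called 6784, 5552 and 41 probe sets, each as the 1 split that large, and the highest of the other splits 0 in all 3. Every other split mixes samples of both groups, so a difference between the groups goes into the spread. The count of 0 therefore cannot stand for chance. For lists the real split called 14, 11 and 8 and the highest other 13, 12 and 10, with 1, 2 and 3 splits as large. The count of lists called therefore did not set the real split apart in +/- against -/- or in +/+ against +/-.

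A first pattern is that -/- sample 4 lay nearer the CD45-positive samples than -/- samples 5 and 8 did. For 360 probe sets at least 10-fold higher in both CD45-positive groups than in samples 5 and 8, the median log2 ratio of sample 4 over those samples was 2.30, and 97.8% were higher. On chip A, where all OGCsort arrays share a lot, it was 2.42, which argues against the lot of the chip B array, and 14474 equally dim probe sets without that difference had a median of 0.081, which argues against a higher background. On chip A sample 4 was also alone at its fluidics station among the arrays of its wash run, and the station was not tested. On chip B samples 4, 5 and 8 shared a wash run and station. Sample 4 still lay at 72.6 on the first principal component there, against 121.2 and 110.7. Its chip B array was of another lot than theirs, so chip B alone does not decide. A candidate explanation is that CD45-positive cells were in that sample, which the gate should remove, at a median of 20% of their level (quartiles 9.06 and 35.6%). The members of that set were higher in sample 4 in the monocyte (2.57, 5 genes), B lymphoid (2.86, 6 genes), MHC class II (2.24, 3 genes), neutrophil granule (2.73, 2 genes) and, less so, T and NK lymphoid (0.75, 2 genes) lists, against medians over all members of -0.05, 2.05, 1.23, 1.41 and 0.27, and it stays open, because the set was picked for low signals in samples 5 and 8.

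A second pattern is that Xist, the RNA of the silenced X chromosome, and Eif2s3y, a Y-linked gene, traded places between samples: with 1 probe set per gene, 10 of 11 samples were over a signal of 100 on exactly 1 of them. Eif2s3y was over 100 in 4 samples, with signals of 336 in -/- sample 8, 464 in +/- sample 1, 572 in +/+ sample 1 and 607 in CPGSE sample 6. Of the other probe sets, 1 each of the Y-linked Kdm5d and Uty was over 100 in the same 4 samples alone, and the other 2 of Xist were lower in these 4 (at most 17.9 and 569) than in the rest (at least 103 and 8410), but the other Eif2s3y probe set, on chip B, was over 100 in 1 of these 4 and 5 of the rest, and the remaining Kdm5d and Uty probe sets did not part the samples either. Both same-numbered pairs of OGCsort sorts were alike, and +/- sample 1 was over 100 on both genes, with 209 for Xist by the probe set used and 17.9 and 399 by the others. This is consistent with animals of both sexes among the sorts, a hypothesis found and tested on the same data.

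Another pattern is the set of plasmacytoid dendritic genes that were higher in +/+ than in +/-. A second list of 19 marker genes, none of them in the fixed lists, had 17 measured, of which 15 were higher, with a median log2 fold change of 1.08 (camera p = 7.75e-11, and p = 0.00792 with an estimated correlation of 0.14). The highest were Cd7 (log2 fold change 2.93, adjusted p = 0.0858), Cox6a2 (2.32, adjusted p = 0.0899) and Upb1 (2.19, adjusted p = 0.301), and none passed over all genes. Within the chip A wash run that held both groups the dendritic list had a median of 1.28, but it held 1 +/+ sample, the one with the highest dendritic level of its group, so the wash run is not excluded. More plasmacytoid dendritic cells in the +/+ sort may also be the source, and higher levels per cell were not tested.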
